A study of Mus musculus with 60 samples.

How the data were processed

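Polyadenylated RNA from the ventral hippocampus of 60 male C57BL/6J mice was sequenced, with 1 library per animal. RNA was extracted with Trizol and libraries were made with an Illumina TruSeq kit, per the labels. The deposited gene table holds estimated counts (expected counts, not normalized) for 13774 gene symbols in 60 animals. The deposited transcript tables hold estimated counts (expected counts, not normalized) for 135175 transcripts in 59 animals, because animal 22 of the CSI home-cage group had none. In every transcript table used here 6 lines were empty. The authors trimmed reads with cutadapt 1.15 and quantified them with kallisto 0.44.0 on GRCm38 transcripts, per the submitters' processing notes.

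The gene table was checked against the transcript tables. For 13773 genes with transcripts, its values were the sums of the estimated counts of protein-coding transcripts, within 0.5 counts for at least 99.985% of the genes of every animal. Genes with low counts had already been left out by the authors: every gene kept reached 1 CPM (counts scaled to the library total) in at least 11 libraries. The transcript tables totalled 7686200 to 22074000 estimated counts, of which protein-coding transcripts held 86.7% to 88.6%. Gene positions, GC content and transcript length came from GENCODE M21 on GRCm38, for 13755 genes (position) and 13745 genes (GC content and length). They were matched by the gene identifier that the transcript tables give for each symbol. The GENCODE release the authors used was not stated in the sources used here, so a gene's position is that of its identifier in M21. No pair among the 1770 library pairs held the same counts.

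Animals were grouped as labelled: control housing in the home cage (24), control housing after restraint (6), chronic social instability (CSI) in the home cage (24) and CSI after restraint (6). No paired analysis was possible because every animal belonged to 1 group and the animal numbers were unique. Animals 1 to 30 were CSI animals and animals 31 to 60 were controls, and the labels gave no batch, day, cage or litter.

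Estimated counts were treated as counts and rounded, an assumption made before the data were examined. The main test was the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM normalization, filterByExpr (which removed 0 genes) and 1 coefficient per group over all 60 animals, so that the groups of 6 shared the estimate of spread with the groups of 24. The contrasts were restraint in each housing, restraint averaged over housing with equal weights, the difference between both restraint effects (the interaction), CSI in the home cage and CSI after restraint. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over 13774 genes. Adjusted p values of genes in the text are from this test unless another tool is named. The biological coefficient of variation was 17.9%. Log2 CPM values used a prior count of 2.

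Before the data were examined, 14 gene lists and 16 lists of cell type and neighbouring tissue markers were fixed. They were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 30 lists of a contrast. Called members were counted over all genes and adjusted over the list alone. The immediate early gene score was the mean log2 CPM of the list's 38 genes. It was compared by exact two-sided permutation tests over 593775 splits within a housing and 924 splits between the restrained groups, and by a two-sided permutation test with 100000 resamples between the home-cage groups. Spread between home-cage animals was tested with limma on absolute deviations of log2 CPM from the group median. Isoform usage was tested with edgeR diffSpliceDGE (gene-level Simes) for restraint averaged over housing on 55376 transcripts of 11233 genes in 59 animals. The similarity of both restraint responses was described by correlations across genes, for which no p is given because genes are not independent replicates.

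Genes to name were also chosen by a rule fixed before the data were examined. For restraint averaged over housing these were the 12 largest rises and the 8 largest falls among called genes with a mean CPM of at least 1. For CSI in the home cage they were the 10 largest rises and falls, and for contrasts with no called gene the 5 smallest p. For spread and isoform usage they were the 5 smallest p, plus Homer1 and Bdnf for isoforms. Up to 4 members with the smallest p could be named per list and contrast, and any member of the list of stress receptors and peptides. Other genes named were chosen after their values were seen, and the text says so.

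Alternatives were DESeq2 1.42.0, median-of-ratios factors, limma voom with quality weights, no filter, a filter of at least 1 CPM in 6 libraries, 5 surrogate variables (sva 3.50.0), marker scores as covariates, all transcripts summed per gene, only the groups compared, leaving out each restrained animal, and leaving out 5 outlying libraries. A library was outlying where its median rank correlation with the others lay more than 3 median absolute deviations below the median. Added after seeing the data were the first principal component, log2 total counts or the protein-coding share as a covariate, protein-coding sums without the authors' filter, correction of each library for GC content and transcript length, and leaving out each home-cage animal. Other splits of the animals into groups of the same sizes were drawn 99 times per contrast and 39 times for isoform usage.

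The methods were tested on simulated data of the same size with 50 changed genes per fold. The simulated genes varied independently of each other, so shares called in the real data may be lower. At a fold of 2, 92% of changed genes were called for restraint in control housing, 98% for restraint averaged over housing, 82% for the interaction and 82% for CSI after restraint. At a fold of 1.5, 72%, 82%, 66% and 50% were called, and at a fold of 1.25, 36%, 66%, 26% and 30%. The test of spread called 84% of 200 genes with an SD raised 3-fold. In the simulated isoform test of 2000 genes, all 200 changed genes and 7 unchanged genes were called. It was smaller and simpler than the real test of 11233 genes, so it does not show how reliable the real calls are. Tables were read with the data.table package (1.17.8), pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and figures were drawn with matplotlib 3.10.9.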

Results

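RNA levels in the ventral hippocampus were measured in 60 male mice that had kept their cage mates (control housing) or had lived under chronic social instability (CSI), with cage mates exchanged at random every week for 7 weeks. In each housing 24 animals were taken from the home cage and 6 were restrained for 30 min and killed 45 min after restraint began. The gene table held estimated counts of genes. Counts assigned to genes totalled 6743140 to 19092611 per animal in control home-cage animals, 9815301 to 15446527 in restrained controls, 10095930 to 19365402 in CSI home-cage animals and 12892074 to 16505633 in restrained CSI animals. The difference in total counts between restrained CSI animals and restrained controls did not pass (exact permutation p = 0.0130, two-sided, adjusted p = 0.0693 over 16 comparisons of library measures).

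The first comparison asked which genes changed shortly after restraint, averaged over both housings. Several transcription factors and the vascular gene Apold1 were among the largest rises. Fos (chromosome 12, 85473890 to 85477273, GRCm38), a subunit of the AP-1 factor, rose 4.27-fold (log2 fold change 2.09 ± 0.14 SE, adjusted p = 7.8e-21). Its mean went from 5.15 CPM (SD 2.02, n = 24) to 22.7 CPM (SD 3.05, n = 6) in control housing and from 5.04 (SD 1.49, n = 24) to 21.02 CPM (SD 2.47, n = 6) in CSI housing. Egr2 (chromosome 10, 67535475 to 67542188) rose 4.22-fold, and Npas4 (chromosome 19, 4984355 to 4990316), a factor induced by neuronal activity, rose 2.72-fold (log2 1.44 ± 0.11). Apold1 (chromosome 6, 134981718 to 134986836), an early response gene of vascular endothelium, had the largest rise of all, 4.54-fold (log2 2.18 ± 0.10, adjusted p = 4.4e-28), from 3.05 to 14.998 CPM in control housing and from 3.54 to 14.9 CPM in CSI housing.

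The other large rises were those of Maff (log2 1.96 ± 0.16), Cyr61 (1.94 ± 0.10), a secreted matrix protein, Fosb (1.44 ± 0.10), the Krüppel-like factors Klf4 (1.32 ± 0.10) and Klf2 (1.30 ± 0.14), Junb (1.03 ± 0.28, adjusted p = 0.0442), Dusp1 (1.02 ± 0.09), a phosphatase that switches off MAP kinases, and the kinase Sik1 (0.97 ± 0.11). Hes5 (chromosome 4, 154960923 to 154962371), a target of Notch signalling, fell most among the genes with a mean CPM of at least 1, to 0.545 of its home-cage level (log2 −0.88 ± 0.18, adjusted p = 0.00256). The developmental zinc-finger factor Zic2 (−0.43 ± 0.09) fell as well, as did Clec2d (−0.65 ± 0.13), the death ligand Tnfsf10 (−0.53 ± 0.10), Klhl6 (−0.42 ± 0.11), the protease Htra4 (−0.39 ± 0.10) and the iron exporter Slc40a1 (−0.34 ± 0.07). With edgeR 90 genes changed, of which 76 rose and 14 fell, and 576 had an unadjusted p under 0.05. Of the 90, 38 changed more than 1.5-fold and 14 more than 2-fold. Junb, Klhl6 and Htra4 lay near the threshold in the main test: their calls were lost in 13, 15 and 15 of 27 recomputations, with adjusted p up to 0.278, 0.337 and 0.324. Junb lay far below it with surrogate variables (log2 0.98, adjusted p = 5.0e-18) and the first principal component (0.99, 3.1e-19). After correction for GC content and transcript length it did so too (1.03, 4.6e-07). Klhl6 (0.0550, 0.0369 and 0.0395) and Htra4 (0.0271, 0.0332 and 0.0811) stayed near the threshold in these 3 settings. Leaving out 1 animal ended the call of Junb for animals 11, 21, 26, 27, 43, 46, 54 and 59 (log2 0.88 to 1.05), of Klhl6 for 11, 17, 26, 27, 43, 54 and 59 (−0.43 to −0.34) and of Htra4 for 17, 21, 26, 27, 43, 46, 54 and 59 (−0.40 to −0.32).

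Of the gene lists fixed before the data were examined, immediate early genes responded most broadly. Of 38 measured members 25 rose, 30 adjusted over the list alone, and none fell. Btg2 (log2 0.89 ± 0.05), an antiproliferative early gene, was among the 4 members with the smallest p. The list as a whole rose (camera adjusted p = 1.1e-152, median log2 0.65), also with an estimated correlation (1.0e-15). Glucocorticoid receptor targets rose too, with 8 of 27 members called and 13 adjusted over the list alone (median log2 0.18, camera adjusted p = 9.5e-39, and 1.1e-06 with an estimated correlation). Among them were Sgk1 (0.93 ± 0.05), a kinase induced by glucocorticoids, the cell-cycle inhibitor Cdkn1a (0.85 ± 0.07), Tsc22d3 (0.87 ± 0.11), which codes for the glucocorticoid-induced leucine zipper, and the NF-kappa-B inhibitor Nfkbia (0.66 ± 0.08).

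Inhibitors of MAP kinase signalling had 4 of 14 members called, also 4 adjusted over the list alone. These were Dusp1, Dusp5 (0.49 ± 0.06), Errfi1 (0.35 ± 0.06) and Dusp6 (0.33 ± 0.07), and the list rose (camera adjusted p = 1.8e-12, and 1.2e-04 with an estimated correlation). In the inflammatory list Nfkbia and Nfkbiz (0.23 ± 0.05), both regulators of NF-kappa-B, were the 2 called of 11 measured members. Adjusted over the list alone 2 were called as well (camera adjusted p = 3.5e-05, and 1.2e-04 with an estimated correlation). The list held 24 genes, and its interleukin, Tnf, Ccl and Cxcl members were not in the gene table. Nfkbia, Errfi1 and the clock gene Per1 were also in the list of glucocorticoid receptor targets, so these lists share called members. Circadian clock genes had 2 called of 16, 3 adjusted over the list alone: the clock repressors Per1 (0.49 ± 0.11) and Bhlhe40 (0.15 ± 0.04). That list passed as well (camera adjusted p = 3.9e-04, and 0.00840 with an estimated correlation, but 0.0732 with an estimated correlation and surrogate variables). Without CSI animal 21 Bhlhe40 missed the threshold (0.14, adjusted p = 0.0505). Nuclear oxidative phosphorylation genes had no called member and a median of −0.03 (camera adjusted p = 0.0165, but adjusted p = 0.542 with an estimated correlation).

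**Figure D1:**
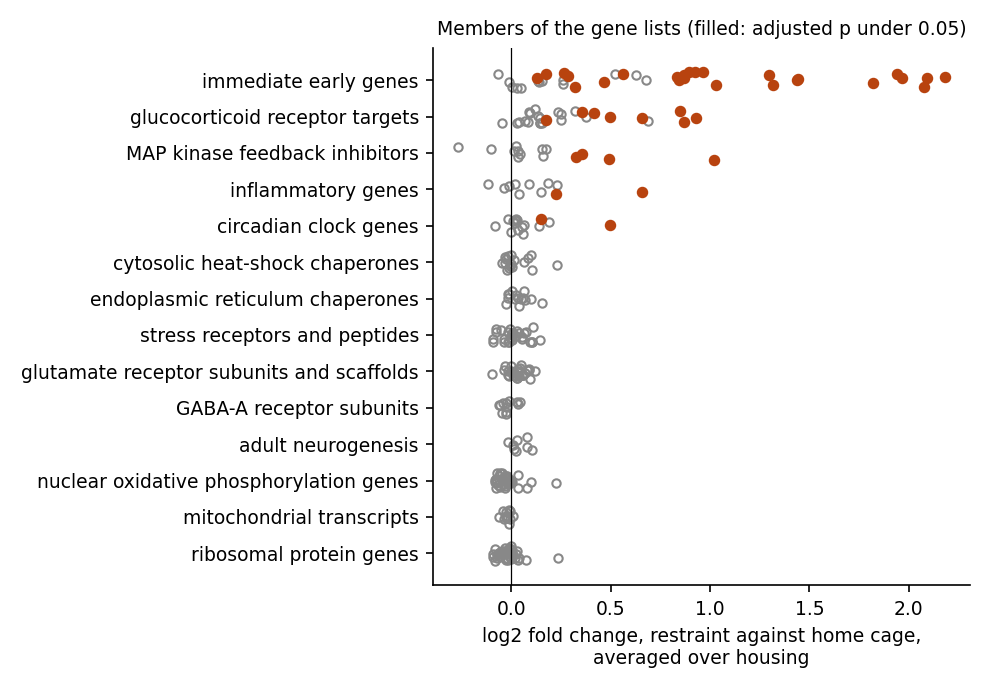
Log2 fold change after restraint, averaged over housing, of the measured members of 14 gene lists; each circle is 1 gene and filled circles have an adjusted p under 0.05. Called members are found in 5 of the lists, with 25 among the immediate early genes.

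Stress receptors and peptides had no called member among 28 after restraint. The glucocorticoid receptor Nr3c1 had a log2 fold change of −0.01 ± 0.05, the mineralocorticoid receptor Nr3c2 0.01 ± 0.04, corticotropin-releasing hormone Crh 0.10 ± 0.14 and its receptor Crhr1 0.10 ± 0.10. No member was called either among 17 cytosolic heat-shock chaperones, 15 endoplasmic reticulum chaperones, 29 glutamate receptor subunits and scaffolds, 12 GABA-A receptor subunits, 8 adult neurogenesis genes, 13 mitochondrial transcripts or 41 ribosomal protein genes, and none of these lists passed camera (adjusted p from 0.0972 to 0.895). Of the marker lists, microglia had 1 called member of 16, also 1 adjusted over the list alone, P2ry13 (−0.29 ± 0.07, adjusted p = 0.0163), a purinergic receptor. Its call was lost without animal 21, 26, 46 or 59 (−0.27 to −0.25). Blood cell genes had no called member of 5, 3 adjusted over the list alone (median 0.32, camera adjusted p = 3.8e-05, adjusted p = 0.0980 with an estimated correlation). Oligodendrocyte markers had no called member of 15 over all genes and 1 adjusted over the list alone. In the lists of astrocyte, oligodendrocyte precursor, endothelial, mural and fibroblast, choroid plexus, ependymal, interneuron, dorsal hippocampus, ventral hippocampus, dentate granule cell, CA3, thalamus and striatum markers no member was called, and none passed camera. For astrocyte markers the median (0.02) and the mean (−0.02) differed in sign, as for mural and fibroblast markers (−0.01 and 0.01) and dorsal hippocampus markers (−0.01 and 0.00), and for interneuron markers the median (0.02) and the direction of the test differed.

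The next comparison addressed the question of the series, whether the response to restraint differed between CSI and control animals. In control housing 43 genes changed (39 rose and 4 fell, 410 with an unadjusted p under 0.05) and in CSI housing 40 (40 rose and none fell, 340 with an unadjusted p under 0.05). Zic2, Tnfsf10 and P2ry13 were among those that fell in control housing. Without restrained control animal 33, 43 or 54, 1 fall was called, and without animal 46, 6; in CSI housing 1 fall was called without animal 11 or 26 and 3 without animal 17. Other models called more falls: 14 in control and 14 in CSI housing with surrogate variables, 12 and 9 with the first principal component, 11 and 8 with limma voom, 12 and 6 after correction for GC content and transcript length, 11 and 4 with the protein-coding share, and 7 and 3 with DESeq2. Of list members, 16 immediate early genes were called in control housing (27 adjusted over the list alone) and 18 in CSI housing (27), and 5 glucocorticoid receptor targets in control housing (7) and 6 in CSI housing (11). Of 30 lists, 10 passed camera in control housing and 6 with an estimated correlation, and 6 and 5 in CSI housing. Blood cell genes (up, 0.0220 with an estimated correlation) and endothelial markers (down, 0.0390, but 0.124 with surrogate variables as well) passed in control housing and not in CSI housing (0.868 and 0.926). The difference between housings did not pass with an estimated correlation for either (0.329 and 0.224). Npas4 rose by the same log2 1.44 in CSI housing and 1.45 in control housing.

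The test of the difference itself called no gene with edgeR (158 with an unadjusted p under 0.05), DESeq2 (152) or limma voom (471). For Npas4 the difference, CSI minus control, was −0.00 (95% interval −0.43 to 0.42), for Fos −0.07 (−0.61 to 0.48), for Apold1 −0.22 (−0.62 to 0.18) and for Egr2 0.47 (−0.14 to 1.08). Sgk1 had a narrower interval (0.04, −0.17 to 0.25), as did Btg2 (−0.03, −0.23 to 0.16). The smallest p belonged to Asap3 (0.61 ± 0.19), the deubiquitinase gene Usp16 (−0.65 ± 0.21), the elongation factor gene Supt4a (0.28 ± 0.09), RP23-115O3.10 (0.35 ± 0.12) and RP23-101H1.18 (−3.32 ± 1.13), each with an adjusted p of 1. These 5 did not pass. With 6 restrained animals per housing, differences below about 2-fold could be missed, as 66% of simulated differences of 1.5-fold and 82% of 2-fold were called.

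Both responses were also compared directly over the 90 genes that changed in the average. All 90 had the same sign in both housings, and Pearson's r across genes was 0.955 (jackknife SE 0.0221, Spearman's rho 0.956), although genes are not independent replicates. The regression slope of CSI on control was 0.998. Choosing genes on the average of both responses can favour equal signs and a slope near 1. Over the 43 genes called in control housing r was 0.975 and the slope 0.952. Over the 40 called in CSI housing they were 0.951 and 0.911. Of the 38 immediate early genes, a list fixed before the data were examined, 35 had the same sign in both housings (92.1%). The sets called in control and in CSI housing shared 31 genes, where independent lists of these sizes share 0.125. Of the 43, 41 had an unadjusted p under 0.05 in CSI housing, and of the 40, 38 in control housing.

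**Figure D2:**
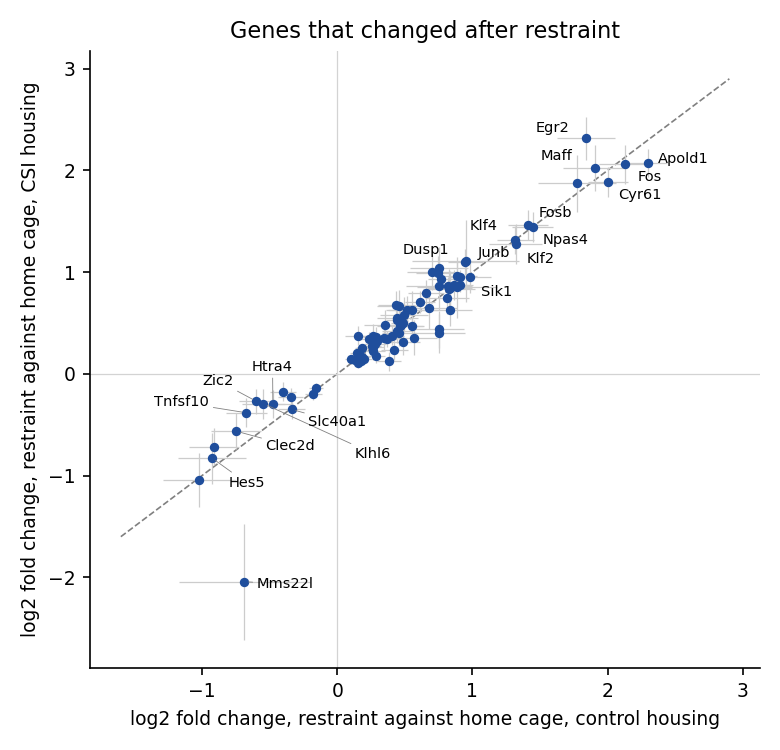
Log2 fold change after restraint in control housing (horizontal) and CSI housing (vertical) of the 90 genes that changed in the average, with bars for 1 standard error and a dashed line of equal change. Mms22l lies farthest from the line (averaged log2 −1.36, adjusted p = 0.0448); it was labelled after its values were seen.

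Single animals were compared by the immediate early gene score, the mean log2 CPM of 38 genes. In control housing the score was 3.53 (SD 0.18, n = 24) in the home cage and 4.31 (SD 0.17, n = 6) after restraint, a difference of 0.77 on the log2 scale (exact permutation p = 1.7e-06, the smallest the splits can give, two-sided, adjusted p = 3.4e-06 over 4 comparisons). In CSI housing it was 3.37 (SD 0.22, n = 24) and 4.16 (SD 0.16, n = 6), a difference of 0.79 with the same p. In each housing 6 of 6 restrained animals lay above every home-cage animal. Restrained CSI animals had a score 0.15 below that of restrained controls (−0.15, exact permutation p = 0.156, two-sided, adjusted p = 0.156), and the rise differed by 0.02 between housings (permutation p = 0.905). In the home cage CSI animals scored lower than controls (−0.16, permutation p = 0.00815, adjusted p = 0.0109, two-sided), and 4 of 24 CSI animals lay above the control median. By the same permutation test that difference was −0.02 (adjusted p = 0.486) after correction for GC content and transcript length. Without the outlying home-cage libraries it was −0.12 (adjusted p = 0.0652), with 23 control and 21 CSI animals left.

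**Figure D3:**
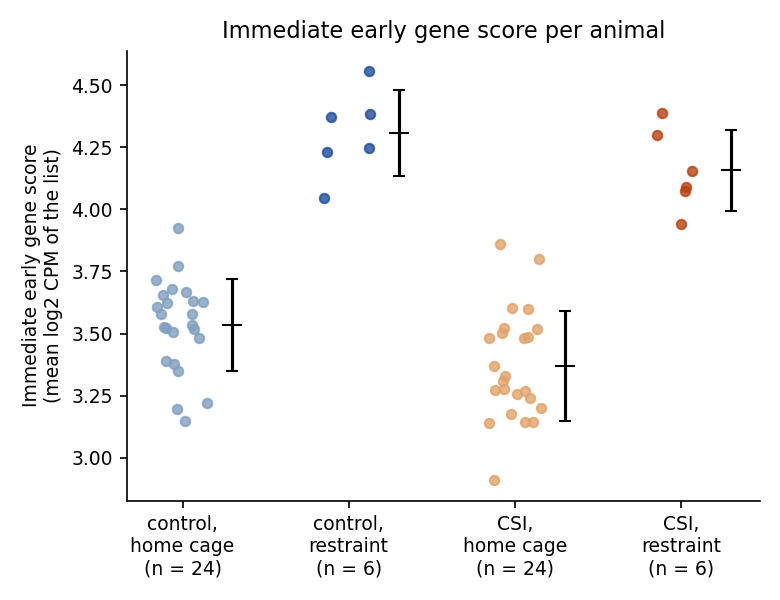
Immediate early gene score (mean log2 CPM of 38 genes) of each animal in the 4 groups, with bars for the mean and 1 SD. All 12 restrained animals lie above every home-cage animal of their housing.

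CSI and control animals were then compared in the home cage, which asks whether the weekly cage changes left a difference at rest. Many small differences were called: 3733 genes, of which 1747 were higher and 1986 lower in CSI animals (27.1% of genes, 6410 with an unadjusted p under 0.05), with a median absolute log2 fold change of 0.19 and 117 over 1.5-fold. Egr3, an early growth response factor, was lower (−0.41 ± 0.10), as were the AP-1 subunits Junb (−0.87 ± 0.26) and Jun (−0.32 ± 0.10), while Homer1, a postsynaptic scaffold, was higher (0.17 ± 0.05), though not after correction for GC content and transcript length (−0.0096). Of the stress receptors and peptides, the neuropeptide Y receptor Npy2r (0.18 ± 0.04), the cannabinoid receptor Cnr1 (0.14 ± 0.04), the oxytocin receptor Oxtr (0.15 ± 0.04) and Nr3c2 (0.08 ± 0.03, adjusted p = 0.0445) were higher, and Crhr1 (−0.28 ± 0.09) and the adrenergic receptor Adra1d (−0.43 ± 0.16) lower. Adra1d changed sign after correction for GC content and transcript length (0.086), with surrogate variables (0.012) and with the first principal component (0.027). Nr3c1 did not pass (0.12 ± 0.05, adjusted p = 0.0540). Adjusted p values of the called genes began at 0.0340, so the calls sat just under the threshold. None of the list members named for this contrast was called with surrogate variables, with the first principal component as a covariate or without the outlying libraries.

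The largest decreases in CSI animals were those of the protease gene Htra1 (chromosome 7, 130936111 to 130985660; log2 −2.76 ± 0.77, from 4.53 CPM, SD 7.42, to 0.679 CPM, SD 2.35, n = 24 each), RP23-300H4.1 (−2.10), RP23-383I16.10 (−1.63 ± 0.59), Hist2h2aa1 (−1.41 ± 0.52), Scand1 (−1.39 ± 0.42), Aup1 (−1.29 ± 0.45), C1qtnf4 (−1.19 ± 0.37), Gm26566 (−1.17 ± 0.36), Pcsk1n (−1.15 ± 0.36), which codes for an inhibitor of a prohormone convertase, and the transporter gene Slc22a17 (−1.15 ± 0.31). The largest increases were those of Xlr3b (0.79 ± 0.29), the acyltransferase gene Lpcat2 (0.62 ± 0.17), RP23-242C19.7 (0.61 ± 0.17), Gm20721 (0.60 ± 0.16), Zbed6 (0.51 ± 0.18), Gpr1 (0.50 ± 0.15), Thoc7 (0.45 ± 0.16), Uxt (0.45 ± 0.18), Gm9747 (0.45 ± 0.16) and Zfp781 (0.43 ± 0.13). None of these 20 passed with the first principal component as a covariate (Htra1 −0.72, Slc22a17 −0.23, Lpcat2 0.59) or without the 5 outlying libraries (Htra1 −2.54, Slc22a17 −1.003, Lpcat2 0.57), and Gm20721, Htra1, Pcsk1n and Slc22a17 passed after correction for GC content and transcript length (adjusted p = 0.0394, 0.0452, 0.0496 and 0.0459). The fitted SE of RP23-300H4.1 could not be computed.

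Of 41 ribosomal protein genes, 12 were lower in CSI animals and 3 higher (20 and 3 adjusted over the list alone), among them Rplp1 (−0.59 ± 0.19), Rplp2 (−0.52 ± 0.17) and Rps2 (−0.20 ± 0.05). The median of the list was −0.15 (camera adjusted p = 0.00238, adjusted p = 0.607 with an estimated correlation). GABA-A receptor subunits had 5 of 12 members higher and none lower (8 higher and 1 lower adjusted over the list alone), such as Gabrb2 (0.19 ± 0.06) and Gabrg3 (0.17 ± 0.05), and a median of 0.14 (camera adjusted p = 0.0202, adjusted p = 0.607 with an estimated correlation). Mitochondrial transcripts had 2 of 13 higher, mt-Nd4l (0.19 ± 0.07) and mt-Co1 (0.14 ± 0.06), 0 adjusted over the list alone (median 0.14, camera adjusted p = 0.0202, adjusted p = 0.607 with an estimated correlation). With surrogate variables mt-Nd4l (−0.017) and mt-Co1 (−0.025) changed sign, mt-Co1 also with the first principal component (−0.021). The medians of the 3 lists changed sign with surrogate variables as well: ribosomal protein genes 0.02 (camera adjusted p = 0.161), GABA-A receptor subunits −0.01 (0.236) and mitochondrial transcripts −0.04 (0.0427, adjusted p = 0.794 with an estimated correlation). The remaining 27 lists did not pass camera. Glutamate receptor subunits and scaffolds had 8 members higher and 6 lower of 29 (9 and 9 adjusted over the list alone), Gria1 among the higher (0.11 ± 0.02) and Grin2d (−0.39 ± 0.10, but 0.14 after correction for GC content and transcript length) among the lower, with a median of 0.04 and a mean of −0.06. Cytosolic heat-shock chaperones had 5 higher and 3 lower of 17 (6 and 3 adjusted over the list alone), with a median of 0.05 and a mean of −0.04. Nuclear oxidative phosphorylation genes had 4 higher and 11 lower of 34 (4 and 13 adjusted over the list alone), immediate early genes 2 and 7 of 38 (2 and 7), glucocorticoid receptor targets 2 and 6 of 27 (2 and 6), stress receptors and peptides 4 and 2 of 28 (4 and 2) and circadian clock genes 0 and 5 of 16 (1 and 5). Oligodendrocyte markers had 5 and 4 of 15 (5 and 6), astrocyte markers 1 and 4 of 14 (2 and 8) and endothelial markers 0 and 4 of 15 (0 and 4). Interneuron markers had 2 higher and 4 lower of 13 (2 and 5 adjusted over the list alone), with Sst (−0.38 ± 0.11) and the vesicular GABA transporter Slc32a1 (−0.49 ± 0.16) lower. Of the lists not named here none had more than 3 called members.

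Libraries differed along a gradient of GC content, and its difference between housings in the home cage did not pass after adjustment. The first principal component held 36.6% of the variance, with a mean of 10.6 (SD 20.6) in control and −12.2 (SD 30.5) in CSI home-cage animals (n = 24 each, permutation p = 0.00374, adjusted p = 0.0598 over 16 comparisons). Across genes, GC content correlated with the log2 fold change of CSI in the home cage (r = −0.738, rho = −0.818) and less with that of restraint (r = 0.153, rho = 0.284), although genes are not independent replicates. The median log2 fold change of CSI went from 0.15 in the genes of lowest GC content (median 39.9%) to −0.31 in those of highest GC content. With the first principal component as a covariate 1 gene was called, Tnfrsf21, a receptor of the tumour necrosis factor family (0.10). Tnfrsf21 was not among the 3733 genes of the main test (0.04, adjusted p = 0.197). With 5 surrogate variables 2 genes were called, Tnfrsf21 (0.09) and the cytoskeletal linker gene Plec (−0.11). Both were named after their values were seen. After correction for GC content and transcript length 342 genes were called, of which 187 were among the 3733. Without 5 outlying libraries (CSI animals 1, 4, 8 and 9 and control animal 37) 0 genes were called with edgeR (2905 with an unadjusted p under 0.05). The folds of the 3733 genes then kept a median of 0.660 of their size. Single animals decided the count as well: it was 0 without control animal 34, 42, 51 or 60 or CSI animal 1, 7, 8, 9 or 25 (smallest adjusted p from 0.0522 to 0.0622). It was 1878 without animal 38, 2000 without 52, 2212 without 5, 2379 without 24, 2447 without 6 or 47, and 5612 without 29.

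**Figure D4:**
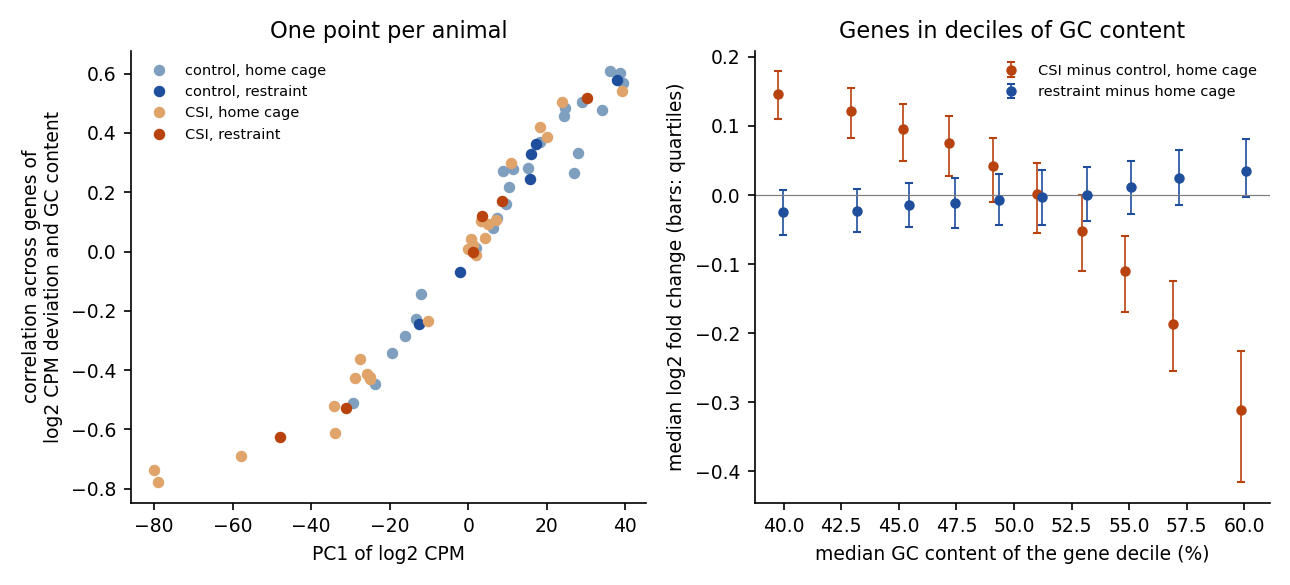
Median log2 fold change of genes grouped into 10 classes of GC content, for CSI against control housing in the home cage and for restraint against home cage. The housing values fall from 0.15 to −0.31 with rising GC content, and the restraint values lie between −0.02 and 0.04.

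Restrained CSI and restrained control animals were compared to see whether housing differed after the stressor. No gene was called with edgeR (326 with an unadjusted p under 0.05, smallest adjusted p = 0.827), DESeq2 (319) or limma voom (882). The smallest p belonged to RP23-101H1.18 (−3.61 ± 1.05), Spink10 (0.97 ± 0.28), Usp16 (−0.64 ± 0.19), Supt4a (0.27 ± 0.08) and the zinc-finger gene Zscan21 (0.31 ± 0.09), none of which passed. No member of any list was called. Blood cell genes had a median of −0.55 (1 lower adjusted over the list alone, camera adjusted p = 9.4e-05, adjusted p = 0.482 with an estimated correlation), mitochondrial transcripts 0.14 (camera adjusted p = 0.0109, adjusted p = 0.955 with an estimated correlation) and endoplasmic reticulum chaperones 0.11 (camera adjusted p = 0.00904, adjusted p = 0.955 with an estimated correlation). With 6 animals per group, 82% of simulated 2-fold differences were called, and the share may be lower in the real data.

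Spread between home-cage animals was compared to ask whether CSI animals differed more from each other than controls did. No gene passed with limma (1190 with an unadjusted p under 0.05, smallest adjusted p = 0.427). The smallest p belonged to Irf2, an interferon regulatory factor, with an SD of log2 CPM of 0.316 in control and 0.108 in CSI animals. It was followed by the glutamine transporter gene Slc38a3 (0.111 and 0.302), Drg2 (0.0823 and 0.278), Rhbdd3 (0.338 and 0.817) and the cation channel gene Trpm4 (0.430 and 0.968). With deviations from the group mean 2 genes passed, Irf2 and Tnfrsf8, both with less spread in CSI animals; Tnfrsf8 was named after its values were seen. Of all genes 67.3% had the larger SD in CSI animals (median SD 0.233 against 0.196), a share that no test was applied to. By the deviations the test used, the share was 66.8%, and 45.0% without the outlying home-cage libraries (3 CSI and 1 control).

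Isoform usage after restraint was tested because Homer1 and Bdnf have known activity-dependent transcripts. A transcript of Homer1 (RP23-262I3.1-003) went from 0.745% to 2.79% of the gene's counts in control housing and from 1.23% to 4.19% in CSI housing (gene-level adjusted p = 0.0419, but 0.123 with the gene-level F test). Bdnf did not pass (adjusted p = 0.690). In all 200 of 11233 genes were called (845 with an unadjusted p under 0.05). Among the genes with the smallest p were Trip4, Slc35f4, Nsmce4a and Bcor. In Trip4 the transcript RP23-177B17.2-001 made up 2.45% of the gene's counts in control home-cage animals and 0 after restraint. With only transcripts that held at least 10% of their gene's counts, 4 of 7881 genes passed, Cenpl, Sgk1, Cage1 and Rbm11, which were named after their values were seen. Other splits of the animals gave as many called genes in 39 of 40 cases, the real split included, with up to 676, so these calls are not told apart from chance.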

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

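The covariate models, the GC correction, the relation to animal number and the leaving out of home-cage animals were chosen after the large count in the home cage was seen, and the test of minor transcripts after the isoform result was seen.

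In each group of 6 restrained animals, total counts, the first principal component, the immediate early gene score and the log2 CPM of the genes with the largest rises and falls after restraint were searched for 1 animal far from the others. Of these 46 sets of values, 2 held such an animal. Fos in control animal 49 was at log2 CPM 4.11 while the other 5 restrained controls lay between 4.503 and 4.73 (gap over range 0.633), so its response was the weakest of the group and still far above the home-cage mean. Klhl6 in control animal 59 was at log2 CPM −0.44 against 0.23 to 0.59 in the others (gap over range 0.653), and without this animal the fall of Klhl6 was not called (−0.34, adjusted p = 0.337). Without animals 11, 17, 26, 27, 43 and 54, in turn, it was not called either (−0.43 to −0.37). Chance gives such a gap in about 1 in 20 groups, and 2 of 46 is no more than that.

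For 10 lists the response to restraint differed between housings by camera with a preset correlation. The response was higher in CSI housing for ribosomal protein genes (adjusted p = 9.1e-06, median difference 0.10, adjusted p = 0.354 with an estimated correlation), endoplasmic reticulum chaperones (0.00226, 0.07, 0.379), glucocorticoid receptor targets (0.00319, 0.07, 0.354), mural and fibroblast markers (0.00939, 0.13, 0.329), nuclear oxidative phosphorylation genes (0.0126, 0.05, 0.379) and endothelial markers (0.0191, 0.03, 0.224). It was lower for choroid plexus markers (0.00264, −0.69, 0.452), blood cell genes (7.4e-04, −0.28, 0.329), ependymal markers (0.0126, −0.17, 0.329) and glutamate receptor subunits and scaffolds (0.0337, −0.03, 0.329). No list passed with an estimated correlation. Choroid plexus scores varied widely between animals, with an SD of 0.64 in control and 0.72 in CSI home-cage animals.

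The first pattern weighed is the set of 3733 genes that differed between CSI and control animals in the home cage. Chance is not excluded. Of 100 splits of the animals 1, the real one, gave as many, and the highest other gave 0. Leaving out each of the 48 home-cage animals in turn, however, gave a count of 0 in 9 cases. The difference in the first principal component between these groups did not pass either (permutation p = 0.00374, adjusted p = 0.0598). The splits therefore cannot exclude a chance imbalance along that component. Different shares of choroid plexus, oligodendrocytes and ventral tissue are argued against, since 5028 genes were called with marker scores as covariates and the fold changes kept 1.01 of their size (quartiles 0.988 and 1.03). These 3 scores did not differ detectably between the groups themselves (0.17, −0.02 and −0.02, permutation p = 0.417, 0.423 and 0.530), and tissues whose scores did differ, such as oligodendrocyte precursors (−0.23), were not used as covariates and stay open. A difference in depth is argued against too: with log2 totals as a covariate the count was 0, but the folds kept 0.968 of their size (0.935 to 1.0001) and the smallest adjusted p went from 0.0340 to 0.0567, so the bound on the count written in advance was wrong for calls this close to the threshold. A gradient shared by most genes may explain most of the 3733 differences. With the first principal component as a covariate 1 gene was called, which was not among the 3733. The folds of the 3733 then kept 0.135 of their size (0.0395 to 0.275). With correction for GC content and transcript length 342 genes were called, 187 of them among the 3733. That correction left 0.225 of the fold (0.0392 to 0.4403).

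What the gradient comes from stays open. With the protein-coding share as a covariate 0 genes were called with edgeR (1834 with an unadjusted p under 0.05) and the folds kept 0.459 of their size (0.389 to 0.553); this share moves with the gradient, so both cannot be told apart. The first principal component correlated with animal number in CSI home-cage animals (r = 0.534, permutation p = 0.00676, adjusted p = 0.0108 over 8 relations, rho 0.517, p = 0.0106, r = 0.455 without the 2 farthest animals) and not detectably in controls (r = 0.0204, p = 0.922). Order of handling could therefore play a part, but numbers 1 to 30 were all CSI animals, so it cannot be told apart from housing. An effect of housing on the brain that runs along the same gradient was not tested and would also be removed by these covariates. The count itself rests on single animals: it was 0 without animal 1, 7, 8, 9, 25, 34, 42, 51 or 60, 1878 without 38, 2000 without 52, 2212 without 5, 2379 without 24, 2447 without 6 or 47 and 5612 without 29.

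The second pattern is the response to restraint. Chance can be excluded in control housing (1 of 100 splits gave as many, 43 against 1 in the highest other), in CSI housing (1 of 100, 40 against 18) and for the average (1 of 100, 90 against 2). The gradient of the first pattern is argued against, because all 90 genes were also called with the first principal component as a covariate. An acute response to restraint is the hypothesis left, although time of day and handling of restrained animals were not labelled. For counts of 0 the splits decide nothing, since 100 of 100 give at least 0. This holds for the interaction (0 with edgeR, 158 with an unadjusted p under 0.05, DESeq2 and limma voom 0, highest other 0), CSI after restraint (0 with edgeR, 326 with an unadjusted p under 0.05, DESeq2 and limma voom 0, highest other 1) and spread (0 with limma, 1190 with an unadjusted p under 0.05, highest other 0). Without the outlying libraries the spread test also called 0 (371 with an unadjusted p under 0.05), which decides nothing either. The share of genes with more spread in CSI animals went from 66.8% to 45.0% without them, to 40.1% with the first principal component removed and to 58.6% with surrogate variables removed. A few outlying libraries or the shared gradient may therefore explain that share; which of them, and why these libraries lie apart, was not tested.

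The third pattern is the set of 200 genes with changed isoform usage. Chance cannot be excluded, as 39 of 40 splits gave as many. The other splits called a median of 292 genes and up to 676, against 200 in the real split. Why random splits gave so many calls was not tested. Minor transcripts estimated at 0 in most libraries may explain the 200 calls, because 4 genes were called with transcripts of at least 10% of their gene's counts. No biological explanation was tested.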

How the results depend on the processing

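The first principal component, the totals, the protein-coding share, the GC correction, and leaving out single home-cage animals were tests chosen after the data were seen, as were the recomputed scores of the home cage and the list tests with surrogate variables. Having no filter and the filter of 1 CPM in 6 libraries removed 0 genes and so say nothing about stability.

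Under all alternatives run the interaction and the CSI effect after restraint had 0 called genes. Counts after restraint rose by more than 1.5 times in control housing with surrogate variables (83), limma voom (78), the first principal component (75) and the GC correction (68), in CSI housing with these (94, 71, 78 and 64) and the protein-coding share (61), and for the average with surrogate variables (164) and limma voom (148). Smaller rises included 63 in control housing with the protein-coding share, and 133 and 112 for the average with the first principal component and the GC correction. The cause was not tested. Leaving out each restrained animal gave 31 to 44 genes in control housing, 35 to 41 in CSI housing and 77 to 91 for the average.

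The CSI effect in the home cage fell from 3733 genes to 2 with surrogate variables, 1 with the first principal component, 342 with the GC correction and, with edgeR, 0 without outlying libraries (2905 with an unadjusted p under 0.05), 0 with log2 totals (5711) and 0 with the protein-coding share (1834). Surrogate variables and the principal component remove the shared gradient by construction; the cause was not tested for the others. Leaving out each home-cage animal gave 0 to 5612 genes, with 0 for animals 1, 7, 8, 9, 25, 34, 42, 51 and 60, and 5612 for 29. DESeq2 called 4312 and limma voom 2493.

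The early gene score in the home cage was −0.023 (adjusted p = 0.486) with the GC correction and −0.12 (0.0652) without outlying libraries. The number of lists passing fell with an estimated correlation to 6 for restraint in control housing and to 0 each for the interaction, the home cage and CSI after restraint; with surrogate variables it was 5 for the home cage, of which mitochondrial transcripts also passed before, then with the opposite sign, and 5 after restraint, all lost with an estimated correlation (smallest adjusted p 0.227 and 0.508). Spread called 2 genes with deviations from the group mean. The correlation of both responses was 0.983 over the early gene list. Isoform calls fell to 4 with transcripts of at least 10% of their gene's counts, where fewer transcripts were tested. The cause was not tested for the rest.

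Of 14973 recomputed values of named genes 14260 kept their side of the threshold, 637 lost the call and 47 gained it. Of those kept, 3969 for the interaction and 4172 for CSI after restraint say nothing about stability, because no gene was called under any setting. For CSI in the home cage 1922 values were kept, 588 lost the call and 27 gained it. For restraint averaged over housing 4197 were kept, 49 lost the call and 20 gained it. Values called in neither setting could change sign and are counted as kept. Of values called in at least 1 of both settings 29 changed sign, all for the CSI effect in the home cage. With all transcripts summed these were Uxt −0.0012 and Atp5j 0.017. With the GC correction they included Homer1 −0.0096, Hspa4l −0.0071, Dnajc3 −0.0014, Dbp 0.068, Cry2 0.073, Adra1d 0.086, Grin2d 0.14, Cox6a1 0.078, Mag 0.0012, C1qa 0.041, C1ql2 0.0015 and Bok 0.33, the last with an adjusted p of 0.0394. With surrogate variables they were Rhob 0.0088, Adra1d 0.012, Gabrb1 −0.0026, mt-Nd4l −0.017, mt-Co1 −0.025, Slc1a2 −0.0048, C1qa 0.0011, Egfl7 0.0015, Gad2 −0.014 and Plk5 0.0051, and with the first principal component Adra1d 0.027, mt-Co1 −0.021, Gad2 −0.0046 and Plk5 0.010. The cause was not tested. An effect of depth on rare genes was not tested.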

Other observations

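The relations of the first principal component within groups were chosen after the data were seen.

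Scores of marker lists (mean log2 CPM) were lower in CSI than in control home-cage animals for 7 of 16 lists, with 24 animals each, by permutation tests adjusted over 64 comparisons. The difference was −0.23 for oligodendrocyte precursor markers, −0.15 for mural and fibroblast markers, −0.15 for striatum markers, −0.11 for dorsal hippocampus markers, −0.10 for interneuron markers and −0.09 for astrocyte markers (adjusted p = 0.0252 each), and −0.05 for endothelial markers (0.0416), whose median log2 fold change was 0.04. None of the 7 lists passed camera in the home cage (adjusted p from 0.133 to 0.751), and the scores were not corrected for the GC gradient between libraries. Blood cell genes were 0.53 higher in restrained controls than in home-cage controls (exact permutation p = 0.0106, two-sided, adjusted p = 0.0717), which did not pass.

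The first principal component followed how strongly a library's values depended on GC content, in control (r = 0.978, rho = 0.962) and CSI home-cage animals (r = 0.956, rho = 0.977). Each had a permutation p of 1.0e-05, the smallest they can give (adjusted p = 2.0e-05 over 8 relations), and r was 0.969 and 0.979 without the 2 farthest animals. It also followed the protein-coding share (r = 0.849 and 0.924, rho = 0.836 and 0.929), with the same p. It did not follow total counts detectably (r = −0.0758, p = 0.723, and r = −0.167, p = 0.437).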
